A study of Homo sapiens with 2 samples.

How the data were processed

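RNA of the human retinoblastoma cell line Y79 was measured on 1-colour Agilent whole human genome expression arrays, 1 array of untreated cells and 1 array of cells treated with cerulenin at 7 µg/ml. The labels give neither the length of the treatment nor how many cultures were pooled. The untreated array is labelled control 2, and any other control array was not analysed here.

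The deposited value table gives 1 intensity per probe for both arrays. Per the labels, signals were extracted with Agilent Feature Extraction 9.1, while the header of the cerulenin array's scanner file names version 9.5.3.1. Per the submitters' processing notes, the data were then scaled in GeneSpring GX 7.3.1 to the 50th percentile of each array. That scaling is not in the deposited intensities. For all 41000 gene probes, the cerulenin column equalled, within 0.01, the raw median pixel signal of the last spot of the probe in that array's scanner file, before any background subtraction or scaling. The untreated array came without a scanner file, so its column could not be set against one. The scanner file of the cerulenin array also gave other deposited columns, its background-subtracted intensity, its mean and local background intensities, and its flags. The labels name a different scanner model for each array, so scanner, slide, labelling and group cannot be told apart.

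The plan written before the data were examined took the values as already scaled by their submitters, which did not hold. A background correction and a scaling were therefore chosen after the signal distributions and the spike-in controls had been looked at, and before genes past the size limits were counted. Background was corrected with limma 3.58.1 in R 4.3.3 by the normexp model with 48 control probes as negative controls, those of the 93 control probes that were mostly not well above background on the cerulenin array, and 50 was added. Each array was then divided by the median of the 24716 probes above the background limit on both arrays, which removed a difference of 0.28 on the log2 scale. The background limit was the mean of the negative controls plus 3 SD. The counts from the deposited values taken literally, with no correction and no scaling, are given beside the main ones.

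A probe entered when the scanner flag called it well above background on the cerulenin array, or when its implied untreated signal reached 19.3, the lowest processed signal among probes with that flag. Control probes and 180 probes flagged as outliers on the cerulenin array were left out, and 34434 probes entered. The flag is lenient, since the lowest median signal with it was 71.5, near the mean of the negative controls. Probes were named through RefSeq accessions (23865 probes), by symbol (2004) or by an older symbol (965), with names of assembly GRCh38.p14, and 14166 probes kept the name in the file. The value of a gene was the median log2 ratio, cerulenin over untreated, over its entering probes, for 26144 genes, of which 15810 had a symbol. Probe coordinates are those of the scanner file, on hg17.

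With 1 array per group no test across samples was possible, and no p-value is given. Genes were set against the submitters' own size limits, a ratio over 1.5 for higher and under 0.55 for lower. For 37 gene lists fixed before the data were examined, the median log2 ratio was placed among 10000 random lists of the same size matched on mean signal in 10 bins, which describes these 2 arrays only. A list was said to stand apart under the 2.5th or over the 97.5th percentile, where 1.85 of the 37 lists would fall by chance if genes of a list varied independently. The genes named were, by a rule fixed beforehand, the 10 highest and 10 lowest with a symbol whose brighter signal reached the median of entering probes, up to 4 members of each list with the largest ratios, and a fixed set of genes whatever their value, among them FASN, ACACA, ACLY, SCD, SREBF1, SREBF2, INSIG1, CDKN1A, DDIT3, ATF3, HMOX1, RB1, MYCN and CRX. For a gene not above the background limit on one array, the ratio is given as a bound, the brighter signal over the higher of the limit and the dimmer signal.

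The scaling, the gene medians and the size limits were tested on simulated data. The untreated array was simulated against itself with the spot noise of the cerulenin array and 200 genes changed by known folds. These genes were drawn only from those with a log2 signal of at least 8 on the brighter array. Differences between arrays beyond spot noise were not simulated, so errors on the real arrays can be larger. In this simulated comparison of 26144 genes, 100% of genes at 4-fold and 98% at 2-fold were past the higher limit, and 70% of genes at 0.5 and 100% at 0.25 were past the lower one. Of 25944 unchanged genes, 482 passed the higher limit and 62 the lower one from spot noise alone. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used for the other steps.

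Alternatives fixed before the data were examined were the median of the genes, the 75th percentile, lowess or quantile normalization between the arrays, no filter or a filter on both arrays, the brightest probe of a gene, the background limit added to both sides, normexp on the mean and local background of the cerulenin array, and 2-fold limits. Chosen after the data were seen were scaling on the 50th percentile of all probes or on 5 spike-in probes, the deposited values without correction, with and without scaling, normexp without negative controls, leaving out the 320 probes saturated on both arrays, and removing the trends of the ratio with probe GC content and with place on the array.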

Results

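Gene expression was compared between Y79 cells, an established human retinoblastoma line that grows in suspension, left untreated or treated with cerulenin, an inhibitor of fatty acid synthase, at 7 µg/ml. Each condition had 1 array, so no difference reported here has a replicate check, and the number of arrays limits the precision. Before correction, the median intensity of the 41000 gene probes was 213 on the untreated array and 229.5 on the cerulenin array. The background limit was 141 and 119 in that order, and 24997 and 27928 probes lay above it. The scanner was saturated at 344 probes of the untreated array and 371 of the cerulenin array, and 320 of them were saturated on both. The true ratio of those 320 is unknown. They were kept in the reported setting, and without them 25993 genes entered.

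The error within an array was measured on the probes printed 10 times on the cerulenin array. The SD of log2 signal between spots of a probe was 0.13 for signals between 10 and 12 on the log2 scale and 0.29 for signals between 7 and 8. Between different probes of 1 gene, the SD of the log2 ratio was 0.36 over the 4355 genes with at least 2 probes above the background limit on both arrays. Of 342 such genes past a size limit, 313 had all probes on the same side of 0. Those genes were called on the median of the same probes, which favours such agreement. Of the 4013 such genes not past a limit, 58.7% had all probes on the same side. The Pearson correlation between the first 2 probes of a gene was 0.44.

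The first comparison asked how many genes differed between cerulenin and untreated cells by more than the submitters' limits. Of 26144 genes, 1527 were higher and 846 lower on the cerulenin array, and 23771 lay between the limits. The split depended on the limits and on the scaling. On the log2 scale the higher limit asks for a smaller change than the lower one. With 2-fold limits in both directions and the same scaling, 318 genes were higher and 441 lower. The median log2 ratio of all genes was -0.20, it was -0.24 with the arrays aligned at their 75th percentiles, -0.33 with the spike-in controls aligned and 0.00 with the 50th percentiles of all probes aligned. Under those scalings 1303, 967 and 3008 genes were higher and 1088, 1661 and 341 lower. With genes centred on their median, 3049 were higher and 331 lower, with lowess 2081 and 505, and with quantile normalization 1944 and 536. With normexp on the mean signal and local background of the cerulenin array, 3007 were higher and 473 lower, and with the background limit added to both sides 1075 and 260. With the deposited values neither corrected nor scaled, 4257 genes were higher and 172 lower. Removing the trend with place on the array gave 1938 higher and 563 lower. The counts in either direction are therefore not settled by these arrays. A scaling that multiplies an array by 1 factor leaves the order of the genes and the place of a list among random lists as they are.

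**Figure D1:**
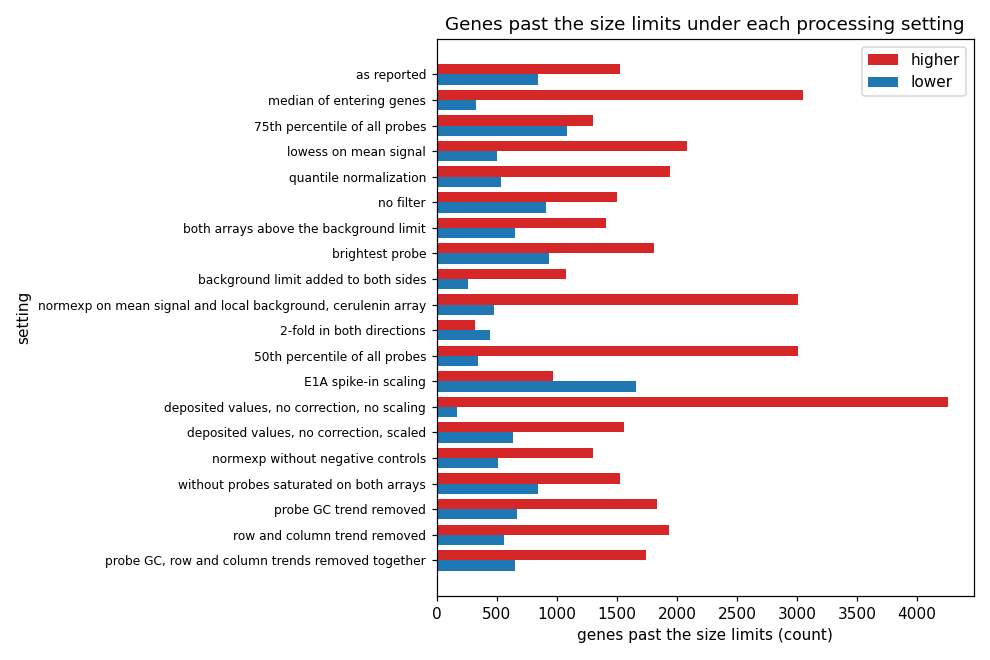
Number of genes past the size limits (horizontal axis, count) under each processing setting (vertical axis), higher on the cerulenin array in red and lower in blue, 1 array per group. The reported setting gave 1527 higher and 846 lower genes, and spike-in scaling was among the settings with more lower genes than higher ones.

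Ratios also followed properties of the probes. Over 24142 probes above the background limit on both arrays, neither saturated nor flagged, the median log2 ratio was 0.06 for probes of the lowest GC content and -0.33 for those of the highest. By the row of the spot on the array, it ranged from 0.05 to -0.22.

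**Figure D2:**
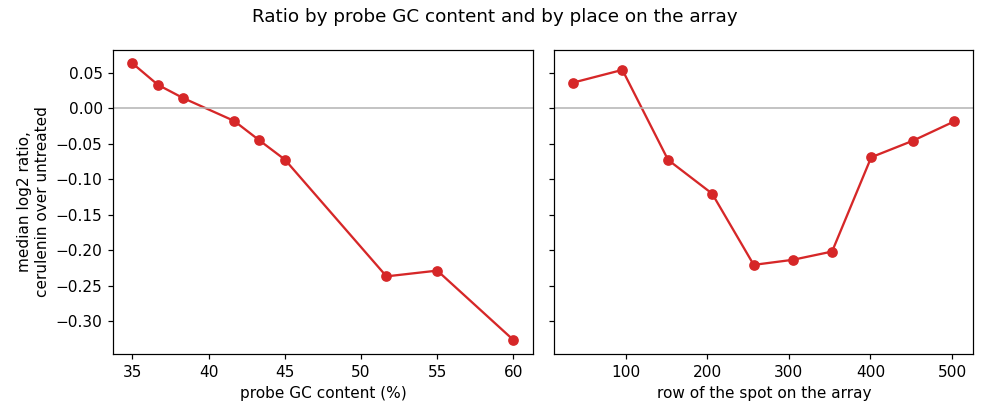
Median log2 ratio of cerulenin over untreated (vertical axis) for probes grouped by GC content in percent (left) and by row on the array (right), each point a group of probes. The median was highest, 0.06, at low GC content and lowest, -0.33, at high GC content.

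Among genes with a symbol and a signal in the brighter range, LCMT2 had the highest ratio, with a log2 ratio of 2.58 and scaled signals of 228 on the untreated and 1358 on the cerulenin array. TFRC followed at 2.13, with its probe at chromosome 3, 197264903 to 197264962 in the hg17 build. The others of the 10 highest were TP53I3 at 1.92, GNGT1 at 1.88, PLEKHG2 at 1.87, NEFH at 1.81, TRAK2 at 1.76, MIR1915HG at 1.71, HPS6 at 1.69 and WTAP at 1.67. The 3 probes of WTAP ranged from -0.28 to 1.82.

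The lowest log2 ratio among these genes was -8.49, of LINC00311, from a single probe with a scaled signal of 44691 on the untreated array and 125 on the cerulenin array. ALDOC followed at -2.32, DDIT4 at -2.16, CREB3L2 at -2.04, EPB41L4A-AS1 at -1.94, AK4 at -1.93, LIMS3 at -1.90, ZBTB16 at -1.80, ASMTL at -1.78 and POTEE at -1.77. LIMS3 and POTEE belong to families of near-identical copies, and their probes can read several of them.

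The second comparison asked whether genes of fatty acid synthesis, the pathway that cerulenin inhibits, stood apart. The 21 measured genes of the list had a median log2 ratio of -0.15, at the 35.2th percentile of matched random lists, with 1 gene higher and 1 lower. FASN had a log2 ratio of -0.11, from scaled signals of 511 and 475. Its probe lay on chromosome 17, from 77630768 to 77631358 in the same build. ACACA was at -0.43, SCD at -0.18 and SREBF1 at -0.78, none past a limit. The only probe of ACLY was flagged as an outlier on the cerulenin array and did not enter. FADS2 was at 0.61, with probes at 0.13 and 1.10, ELOVL2 at 0.56, MLXIPL at -0.62 and ACACB at -0.98. The cholesterol list had a median of -0.12 over 25 genes, at the 16.5th percentile, with INSIG1 at -0.46 and SREBF2 at -0.52. The lists of fatty acid oxidation, phospholipids, sphingolipids and lipid transport lay between the 37.0th and 64.8th percentile. Past the higher limit in them were DECR1 at 1.24, ACAD9 at 0.85, SPHK2 at 1.46 and DEGS1 at 0.94, among others.

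Of the 37 lists, 7 stood apart. Hypoxia and glycolysis genes had the median log2 ratio -0.48 over 34 genes, where none of the 10000 random lists was as low, with 11 genes lower and 2 higher. These counts depended on the scaling, with 6 lower and 4 higher at the 50th percentile of all probes and 13 lower and 0 higher with E1A spike-in scaling. ALDOC was at -2.32, P4HA1 at -1.41, PDK1 at -1.32 and VEGFA at -1.26, the last with all 4 probes between -1.69 and -1.10. The 19 genes of the list with 1 probe had a median of -0.53, with 6 of them lower. The 15 genes with several probes had a median of -0.15, at the 17.6th percentile, with 5 of them lower. The difference between these sets was not tested. Histone genes had the median -0.55 over 47 genes, where again none of the random lists was as low, with 7 lower and 0 higher, against 6 and 2, and 12 and 0, under the same 2 scalings. H2BC12 was at -1.73, H2AC18 at -1.52, H1-4 at -1.20 and H2BC11 at -1.17. Histone genes are near-identical copies, so that a probe can read several of them, and the histone probes had a median GC content of 53.3%, against 43.3% for all entering probes.

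Targets of p53 had the median -0.37 over 25 genes, at the 0.04th percentile, and went both ways, with GDF15 at -1.48, PLK3 at -1.05 and GADD45A at -0.97 but TP53I3 at 1.92 and CDKN1A at 0.50. Genes of the unfolded protein and integrated stress responses had the median -0.24 over 34 genes, at the 1.3th percentile, with 5 higher and 3 lower. These counts too depended on the scaling, with 7 higher and 2 lower at the 50th percentile of all probes. In that list CREB3L2 was at -2.04, DDIT3 at -1.32, CTH at -0.88 and SDF2L1 at 0.83, and ATF3, named in any case, was at -0.58. Under lowess on the mean signal this list lay at the 20.9th percentile and p53 targets at the 3.3th. Heat shock genes had the median 0.22 over 25 genes, at the 99.4th percentile, with 3 higher and 1 lower. At the 50th percentile of all probes 7 were higher and 0 lower. CHORDC1 was at 0.70, but HSPA1A was at -1.02, DNAJB1 at -0.69 and HSPA6 at -0.68. The 3 probes of HSPA1A ranged from -1.08 to 0.06. Cone photoreceptor genes had the median 0.16 over 13 genes, at the 99.7th percentile, with PDE6H at 0.96. None of these genes had several probes, so their values have no check between probes. With no filter the median was 0.04 over 15 genes, at the 98.35th percentile. The ribosomal protein list also stood apart, at -0.28, but 27 of its 55 genes were saturated on both arrays, and its median is the scaling difference. Without probes saturated on both arrays, the 28 genes left had a median of -0.22, at the 0.82th percentile, with none past a limit.

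**Figure D3:**
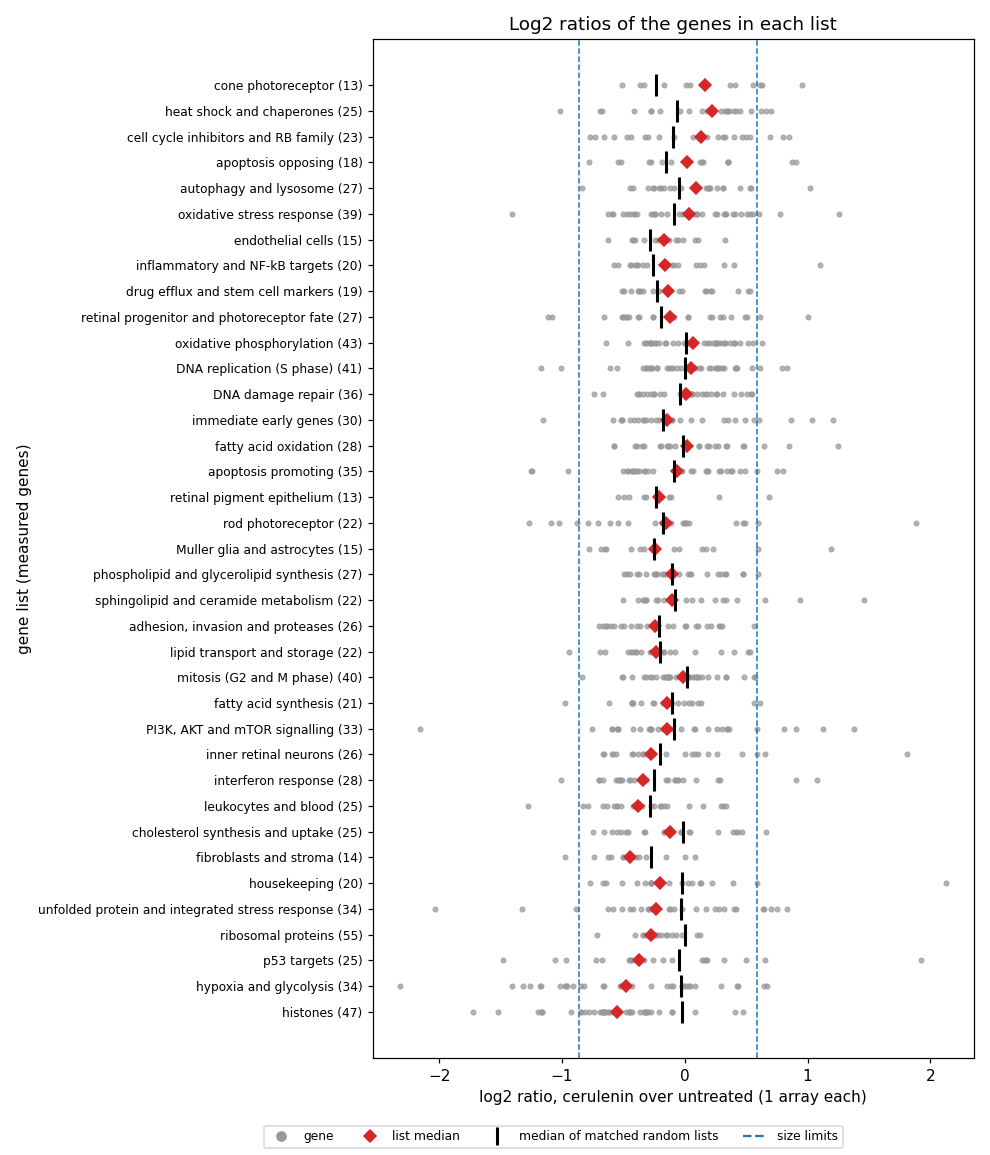
Log2 ratio of cerulenin over untreated (horizontal axis) for the genes of each list (vertical axis, with the number of measured genes), 1 array per group. Grey points are genes, red diamonds the list medians, black bars the medians of matched random lists and dashed lines the size limits, and histones at -0.55 and hypoxia and glycolysis at -0.48 had the lowest medians.

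Lists of cell death and the cell cycle did not stand apart under the reported setting. Genes promoting apoptosis had a median of -0.06, at the 61.9th percentile, with BCL2L11 at -1.24, HRK at -0.95 and CYCS at 0.80. BBC3 was lower, at -1.26, with 1 of its 3 probes saturated on both arrays. Genes opposing apoptosis lay at the 92.1th percentile. None of the 40 mitosis genes and none of the 36 DNA repair genes passed a limit under the reported setting, but 3 and 5 of them were higher with scaling at the 50th percentile of all probes, and 1 of each was lower with E1A spike-in scaling. DNA replication genes had a median of 0.05 over 41 genes, with CDT1 at -1.18, LIG1 at -1.01 and E2F1 at 0.83. Cell cycle inhibitors and the RB family lay at the 97.4th percentile, and stood apart with no filter, with both arrays above the background limit and with the GC trend removed, at the 97.535th, 98.03th and 99.01th percentile, with RB1 at -0.32. MYCN was at 0.29. Rod photoreceptor genes went both ways around a median of -0.15, with PRPH2 at -1.27, NRL at -1.09, GNAT1 at -1.02 and GNGT1 at 1.88, and CRX was at -1.09. In signalling lists, TSC1 was at 1.38, RPTOR at 1.13, NFKB1 at 1.11 and JUN at -1.16. HES1, of the retinal progenitor list, was at -1.11. MYC was at 0.87, with probes at -0.27 and 2.00. NQO1 was not above background on the untreated array and at least 1.62-fold higher on the cerulenin array, and HMOX1 was at 0.03. Every other list lay between the 3.7th and 92.1th percentile.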

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

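Control probes outside the gene measurement were compared between the arrays after they had been seen, and 2 of 15 that were above the background limit and unsaturated on both passed the higher size limit. The probe named AT_ssH_TR_3 had a log2 ratio of 2.28, from raw signals of 4138.5 on the untreated and 24267 on the cerulenin array, and the probe named AT_ssH_PC_3 had a log2 ratio of 0.62. The files do not say which transcripts these probes measure, and no explanation was tested.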

How the results depend on the processing

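No paired analysis was possible with 1 array per group, nor leaving out a replicate or splitting the samples another way.

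Scaling on all probes or on spike-ins, the deposited values without correction, normexp without negative controls, the saturation filter and the trend removals were chosen after the data were seen. The number of genes higher, 1527, became 3049 with genes centred on their median, 3007 with normexp on the cerulenin array's mean and local background, 318 with 2-fold limits, 3008 with the 50th percentile of all probes, 967 with spike-in scaling and 4257 with the deposited values unscaled. The number lower, 846, became 331, 473, 441, 341, 1661 and 172 under those settings, 505 with lowess, 536 with quantile normalization, 260 with the background limit added, 514 without negative controls and 563 with the row and column trend removed. Centring and scaling move every gene by 1 constant, and the other causes were not tested.

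Hypoxia and glycolysis, histones, heat shock and cone photoreceptor genes stood apart under all 18 alternatives run on lists. Not all of the 18 are checks. Centring genes and aligning arrays at a percentile or on spike-ins shift every gene equally, which leaves each list's place among random lists unchanged. So does scaling the deposited values. The difference of the hypoxia and glycolysis list from random lists, -0.45, shrank to -0.26 with lowess and with quantile normalization and to -0.27 with the GC, row and column trends removed. The difference of p53 targets from random lists, -0.33, became -0.16 with lowess, -0.18 with quantile normalization and -0.13 with normexp on the cerulenin array's mean and local background, and the list no longer stood apart. That of the unfolded protein and integrated stress response list, -0.21, became -0.069 with lowess, -0.11 with quantile normalization, -0.090 with the brightest probe, -0.17 with the background limit added, -0.044 with normexp on the cerulenin array, -0.13 with the deposited values, scaled or not, -0.11 with the GC trend removed, -0.15 with the row and column trend removed and -0.050 with all 3 removed, and no longer stood apart. The difference of the ribosomal list, -0.28, came to 0.00 under quantile normalization, which gives saturated probes the same value. Without probes saturated on both arrays it was -0.23 over 28 genes and the list stood apart. The causes of the other changes were not tested. Of 540 values of the other 30 lists, 7 stood apart only under an alternative, 3 of them of cell cycle inhibitors and the RB family.

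Of 3061 values of 171 named genes, 2963 moved by less than the SD between probes. Another 96 moved by more without a called gene changing sign, and 2 changed sign. Centring and aligning shift genes by less than that SD, so they are no checks here, nor is the brightest probe for single-probe genes. MYC, with probes that disagreed, came to -0.27 without the filter, and WTAP to -0.28 with its brightest probe. Spot noise was larger for log2 signals under 8 than for brighter ones.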

Other observations

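The test of genes with several probes and the test of DNA replication genes were chosen only after the result was seen, as were the trend corrections as alternatives. Only patterns seen in these 2 arrays were tested, and scanner, slide, labelling, culture and treatment cannot be told apart in any of them.

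The lower median of hypoxia and glycolysis genes was set against the trends of the ratio. With the GC trend removed the list lay at percentile 0 of matched random lists, with a median of -0.27, and with the row and column trend removed also at 0, with a median of -0.36. The median of matched random lists rose as well, from -0.03 to 0.04 under either removal, so part of the change was shared with random lists. Either trend accounts for part of the list's original distance from random lists, but not for its place among them. Faulty spots stay open. With each gene given by its highest probe, the list lay at the 0.01th percentile, but 19 of its 34 genes have 1 probe and cannot move under that rule. Over the 15 genes with several probes, that rule gave the 21.53th percentile, but their ordinary median, at the 17.6th, did not stand apart to begin with, so neither value decides. A second list of hypoxia-responsive genes, none of whose values had been seen, was written before it was measured. Its 27 measured genes had a median of -0.43, with 4 genes lower and 1 higher. RORA was at -1.16 and TXNIP at -1.12, while CA12 was at 0.65, genes named after their values were seen. With GC, row and column trends removed the median was -0.32, at the 0.01th percentile, with 3 genes lower and 0 higher, and CA12 was at 0.58. A candidate explanation is a weaker hypoxia response in the cerulenin culture than in the untreated one. It would not tell a direct effect of cerulenin from a difference in cell density or medium between 2 cultures.

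The lower median of histone genes also lay at percentile 0 with the GC trend removed, at -0.38, and at percentile 0 with the row and column trend removed, at -0.51. Fewer cells in S phase could not be excluded or shown: DNA replication genes lay at the 75.3th percentile, but their median of 0.05 lies over genes that go both ways. Of 11 measured histone variants with polyadenylated transcripts, most of them seen beforehand, the median was -0.26, at the 6.87th percentile, with saturated probes included. Without probes saturated on both arrays, 10 variants had a median of 0.16, at the 84.5th percentile. With GC, row and column trends removed and saturated probes kept, the 11 had a median of 0.01, at the 38.2th percentile. That median was the value of H3-3B, which before the removal had the ratio of saturated probes, -0.28. The medians therefore set no direction for these variants. Cross-reading between histone copies and the efficiency with which transcripts lacking a poly(A) tail were labelled were not tested.

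Of all probes, 5 had a log2 ratio beyond 2.5 in either direction. The probe of LINC00311, at -8.49, and 1 of 5 probes of HSD17B1, at -5.07, lay 3 rows and 1 column apart on the array, and 0.051% of random probe pairs lay as close or closer. The other 4 probes of HSD17B1 lay between -0.57 and 0.95. The 54 other probes within 6 rows and 2 columns of the LINC00311 probe had a median of -0.33 and none was under -1.69, while the median of the rows around it was -0.21. Another of the 5 probes, of AA701368, was saturated on the untreated array and not above the background limit on the cerulenin array, so that its ratio is only a bound, and lay elsewhere, in row 525 against row 312 for LINC00311. The closeness was noticed before it was computed, and these genes were chosen after their values were seen. No explanation was tested.

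To show how often sets of genes stand apart on these arrays, the same comparison with random lists was made for 54 families of genes whose symbols share their opening letters, each with at least 20 genes above the background limit on both arrays. Of these, 8 stood apart where 2.7 would by chance if genes varied independently, and 10 did with GC, row and column trends removed, 7 of them in both. The 57 genes with symbols in OR had a median of -0.45, at percentile 0, and the 330 in ZNF a median of 0.08, at percentile 100. Families chosen by name alone thus reach the same percentiles as the hypoxia and histone lists, so a percentile alone does not show that a list is unusual. The families in RPL and RPS, of ribosomal proteins, were among the 8. Their medians, -0.28, equal the ratio of probes saturated on both arrays. The largest distance of a family's median from that of its random lists was 0.28, of UBE. With these trends removed it was 0.25, of RPL, followed by AP at 0.24. Histone genes lay clearly beyond it, at 0.53 and 0.46. Hypoxia and glycolysis genes lay at 0.45 and 0.27, so with the trends removed they were hardly beyond the largest family. Under the reported setting, differences of p53 targets, -0.33, and cone photoreceptor genes, 0.40, were larger than that of any family. For the cone list this is not a like comparison. It had 13 genes, 9 of them with both arrays above the background limit, while each family had at least 20 such genes. A median of fewer and dimmer genes can vary more. Differences of heat shock genes, 0.28, and ribosomal proteins, -0.28, were about as large as the largest. That of the unfolded protein and integrated stress response list, -0.21, was smaller. The value of ribosomal proteins is no separate comparison, since the families in RPL and RPS hold ribosomal protein genes too.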
